A study of Mus musculus with 9 samples.

How the data were processed

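Lenses of mice at 15.5 days post conception were collected for 9 libraries, 3 each of inbred wild type, mixed-background wild type and conditional knockout (cKO). Per the labels' protocols, each biological replicate held 30 lenses, total RNA was isolated with a kit, and libraries were made with an Illumina TruSeq RNA kit. CASAVA 1.8.2 is named in the submitters' processing notes. The aligner, the annotation and the genome build are not given in the sources used here. Per the file headers, the authors deposited an RPKM value and a normalized expression value for each gene and library, and exon lengths in the inbred files. The inbred files had 7700 rows, of which 24 with 12 repeated symbols were left out. The mixed wild type and cKO files had 190 genes.

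The deposited RPKM values are scaled by exon length and by the library's mapped reads. RPKM multiplied by exon length fell on whole multiples of a single step per library (100% of the low values used, within a tolerance of 0.1 reads), which gave the depth of each library (M, mega, with exon lengths of the inbred files for the shared genes): 16.7, 16.3 and 14.1 M reads in inbred wild type, 38.7, 43.2 and 44.1 M in mixed wild type and 27.4, 25.9 and 26.0 M in cKO. Listed genes held 86.8% to 87.1% of the reads of the inbred libraries. Replicates differed by more than sampling noise in every pair (chi-square per degree of freedom 6.96 to 54.5). The authors' normalized expression values, a score with no stated unit, were multiples of 1/8 in the inbred files and of 1/9 in the other files, and the 3 inbred libraries had the same highest value. Separate quantile normalizations of whole counts would give such values, which was not tested. These values were therefore not compared between the file types except per RPKM.

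Genes were joined by symbol, and 128 of the 190 were found in the inbred list. Group differences were tested with limma 3.58.1 (R 4.3.3) on log2(RPKM + 0.5) with a mean-variance trend, over genes with a mean of at least 1 RPKM in the libraries compared, and adjusted by the Benjamini-Hochberg method at 0.05. The design had named a count test first, and this one for RPKM, which is not a count. Each comparison used only its own 6 libraries. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so p-values come from limma. On simulated values for the 190 genes, the cKO against mixed wild type test recovered 90% of changes of 1.5-fold and 100% of changes of 2-fold or 4-fold, and called 0% of unchanged genes. For mixed against inbred wild type over 128 genes it recovered 95%, 100% and 100%, and called 1.5% of unchanged genes. For cKO against inbred wild type these were 85%, 95%, 100% and 7.4%.

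The 24 gene lists, the comparisons, most alternatives and the rule for named genes were fixed before the data were examined. Genes were named if they were called, all 3 libraries of a group lay beyond the 3 of the other, and their mean over the 6 was at least 2 RPKM: the 12 largest rises and falls for the knockout and 8 for comparisons with inbred wild type. To these were added up to 4 genes per list with the smallest adjusted p, Zeb2, the sex-linked list and some genes of the strain list, Bfsp2 and Nnt among them. Lists with at least 4 measured members were tested with camera at an inter-gene correlation of 0.01. The alternatives were quantile normalization, median centring, limma without trend, no filter, a mean of at least 2 RPKM, pseudocounts of 0.1 and 1, minimum folds of 2 and 2.5, all 9 libraries in a joint fit, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Added after the data were seen were the normalized values with a pseudocount of 10, RPKM rescaled to them, the removal of genes whose normalized value per RPKM was under 0.5 of the typical value (which also drops genes without an exon length, those outside the inbred list), and only genes in all 9 libraries.

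Sequence sharing was measured as the percentage of 31-base words of a gene's longest transcript that occur in transcripts of other genes in GENCODE M21 (GRCm38). This annotation, to which all 190 symbols matched, was used only for sequence sharing, names and the order of neighbouring genes, since its build may differ from the authors'. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps.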

Results

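To determine how loss of Sip1 changes gene expression in the developing lens, RNA from mouse lenses at 15.5 days post conception was sequenced from 3 groups of 3 libraries. Each library came from 30 lenses. Sip1 is the protein product of Zeb2, a zinc finger transcription factor. The conditional knockout (cKO) lenses carried floxed Zeb2 alleles and the MLR10Cre transgene, which expresses Cre recombinase in lens cells. The mixed wild type lenses carried the floxed alleles without Cre and shared the mixed genetic background of the cKO. The inbred wild type lenses came from a C57Bl/6 substrain. Depth, recovered from the steps between RPKM values (reads scaled by exon length and by the total of mapped reads), was 14.1 to 16.7 M reads in inbred wild type, 38.7 to 44.1 M in mixed wild type and 25.9 to 27.4 M in cKO. The inbred tables listed 7676 genes once each. The tables of the other groups listed 190 genes, and 128 of these were also in the inbred list. In every one of the 190 genes the cKO and mixed wild type means of the authors' normalized expression values differed by at least 2.505-fold. This list was therefore chosen on the same libraries, and counts of changed genes within it are not independent evidence of their number or direction.

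The inbred libraries described the wild type lens at this age. Crystallins, the structural proteins of lens fibre cells, took 37.2% ± 1.68 (SD, n = 3) of the reads of listed genes. All 16 crystallins of the fixed list were present, led by Cryaa at 89016 ± 2774 RPKM (SD, n = 3) and Cryga at 41613 ± 2690 RPKM. Crybb2, at 5.62 ± 2.58 RPKM, was the lowest of them. Of the 32 genes for fibre cell membrane, cytoskeleton and maturation, 28 were listed, among them the lens water channel gene Mip at 3622 ± 60 RPKM and the beaded filament genes Bfsp1 at 1473 ± 60 RPKM and Bfsp2 at 1449 ± 120 RPKM. Lens epithelial genes were present as well, 18 of 21, with Foxe3, a transcription factor gene of the lens epithelium, at 136 RPKM. Cell cycle and replication genes were listed for 30 of 32 members. Of the signalling lists, 14 of 32 Wnt genes, 11 of 32 TGF-beta and BMP genes, 11 of 19 Notch genes and 12 of 18 FGF and MAPK feedback genes were listed, with the secreted Wnt inhibitor gene Sfrp1 the highest at 287 RPKM. Also listed were 24 of 32 matrix and integrin genes, 17 of 26 p53 targets, 10 of 21 genes of epithelial-mesenchymal transition, 14 of 29 immediate early and stress genes and 28 of 30 ribosomal and housekeeping genes. Of the lists for other cell types, the inbred list held 1 of 22 retinal genes (Hes5, 3.36 ± 0.39 RPKM), 1 of 18 pigment cell genes (Mitf, 3.05 ± 0.18 RPKM), 3 of 25 periocular mesenchyme genes, 3 of 26 neuronal genes, 2 of 21 muscle genes, 9 of 20 endothelial genes, 9 of 20 erythroid genes and 0 of 26 macrophage and leukocyte genes. Only 4 of 67 surface ectoderm and keratinocyte genes were listed, with Cdh1 (E-cadherin) the highest at 35.0 RPKM. The lowest mean in the inbred list was 2 RPKM, so a gene outside it was either below that level or left out by another rule.

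**Figure D1:**
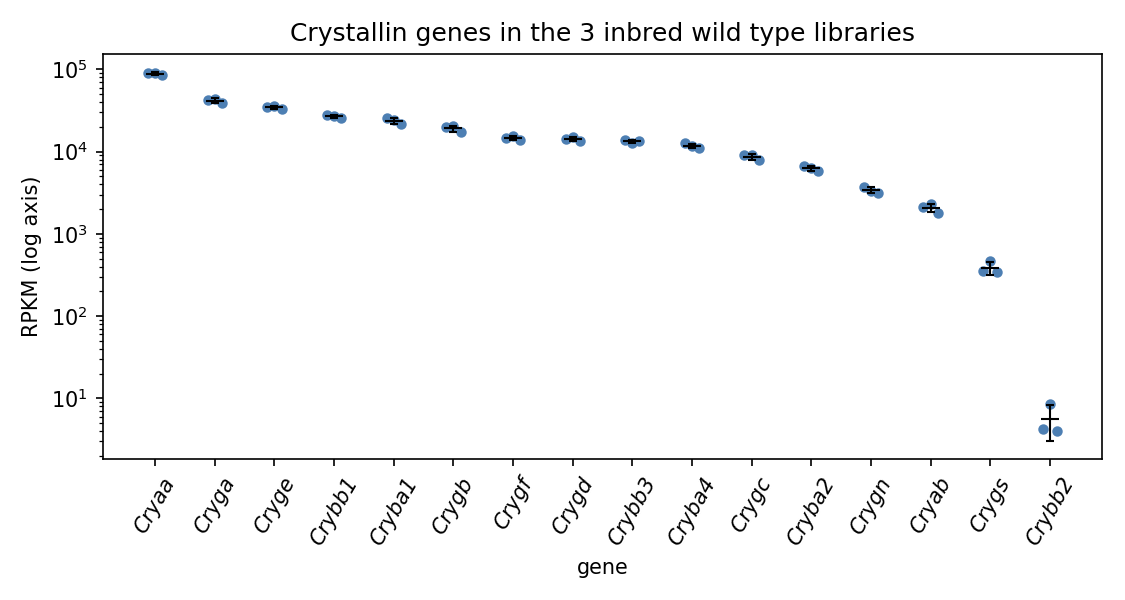
Expression of the 16 crystallin genes in the 3 inbred wild type libraries (points, RPKM on a log axis, genes on the horizontal axis), with mean and SD in black. Cryaa, at 89016 RPKM, was the highest and Crybb2, at 5.62 RPKM, the lowest.

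Zeb2 itself was present in all 3 inbred libraries, at 5.16, 5.96 and 6.31 RPKM (mean 5.81 ± 0.59, SD, n = 3). It was not among the 190 genes used here for the mixed wild type and cKO libraries, so the knockout labels could not be checked against the targeted gene. Of the sex-linked genes, Xist (15.7 ± 2.13 RPKM), Eif2s3y (5.02 ± 0.33 RPKM), Ddx3y (2.49 ± 0.55 RPKM) and Kdm5d (2.02 ± 0.27 RPKM) were all listed in the inbred libraries, which pooled 30 lenses each. No sex-linked list gene was among the 190. Nnt, which carries a deletion in some C57Bl/6 substrains, was at 6.36 ± 0.44 RPKM.

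The comparison of cKO with mixed wild type asked which genes respond to loss of Sip1 on a matched background. The groups also differ in the Cre transgene and in depth. Effects of these, or of a library batch, which the labels do not give, cannot be told apart from loss of Sip1. Of 67 surface ectoderm and keratinocyte genes, 4 were among the 190, and all 4 were higher in cKO lenses. A list gene is called measured if it is listed in all libraries compared. List genes outside the 190 have no values in these groups, so counts of measured genes do not describe a whole list. Krt8 and Krt18, keratins of simple epithelia, rose from 0.075 ± 0.012 to 5.33 ± 1.11 RPKM (SD, n = 3) and from 0.58 ± 0.24 to 5.27 ± 0.83 RPKM. Dsp (desmoplakin) rose 6.83-fold and Dsc2 (desmocollin 2) 3.33-fold, both genes of desmosomal junctions. The crystallin gene Crygs rose 8.95-fold, from 416 ± 41.3 to 3725 ± 454 RPKM. Of 4 measured fibre cell genes Birc7 fell 4.08-fold, Dnase2b, the nuclease that degrades fibre cell DNA, 3.24-fold and Lctl 2.24-fold in cKO, while Lgsn rose. Neither list passed its group test, which set it only against the other listed genes, all chosen for a difference.

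Across the 190 genes, limma called 189 at an adjusted p under 0.05, with 103 higher and 86 lower in cKO. The balance depended on which genes were counted: 43 higher and 84 lower among genes in all 9 libraries, 39 and 61 of these without genes of a low normalized value per RPKM, and 96 and 36 of the 190 at 2.5-fold or more. The remaining gene, Rpl19, had a log2 fold change of -0.18 (SE 0.09, limma adjusted p = 0.0666). Its call depended on the setting: Rpl19 was called lower under median centring (-1.06), with rescaled RPKM (-0.46), in the normalized values (-1.84) and without mixed replicate 1 (-0.21), and higher under quantile normalization (0.44). In all 190 genes the 3 libraries of either group lay on separate sides. Chance gives 10% of unselected genes, a value that does not apply to genes listed for a difference between these libraries. Of the called genes, 169 changed by 2-fold or more. Log2 fold changes are on the log2(RPKM + 0.5) scale, which understates changes of low genes, as are minimum folds, and the folds printed for genes are ratios of mean RPKM without the added 0.5.

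The largest rises were spread over genes of different functions. Of the 12 named, only Uchl1 and Myh7b were in the inbred list. The others were low in mixed wild type, could hardly be listed except by a rise, and could not be compared with inbred wild type. Mt1, a metal-binding metallothionein, rose from 0.92 ± 0.28 to 87.2 ± 13.2 RPKM (SD, n = 3; log2 fold change 5.95, SE 0.16, limma adjusted p = 1.42e-10). Ucma, a cartilage matrix gene, was at 13.9, 14.4 and 16.4 RPKM in the cKO libraries and at 0.09, 0.10 and 0 in mixed wild type. The insulin-like growth factor binding gene Igfbp2 and its relative Igfbpl1 rose 44.0-fold and 29.8-fold. Aass, an enzyme gene of lysine breakdown, rose 86.3-fold, and Pde6b, a phosphodiesterase subunit of rod photoreceptors, rose 49.6-fold. The slow skeletal muscle troponin gene Tnnt1 rose 44.2-fold and the myosin gene Myh7b 11.5-fold. Dlk1, which encodes a membrane protein related to Notch ligands, rose 39.1-fold, the semaphorin receptor gene Plxna2 26.7-fold and Enc1 17.0-fold. Uchl1, a ubiquitin hydrolase abundant in neurons, was the most abundant of the 12, rising from 147 ± 9.18 to 2086 ± 138 RPKM.

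The largest falls by the same rule were also spread over genes of different functions. Actn2, an actin crosslinker of muscle, fell 7.71-fold (log2 fold change -2.52, SE 0.20, limma adjusted p = 2.92e-07). Cnrip1, a cannabinoid receptor binding protein gene, fell 6.30-fold, the sodium channel gene Scn11a 5.51-fold, Rcan2, a regulator of calcineurin, 4.30-fold, Pgm5 3.81-fold and Dpysl2, a regulator of microtubules, 3.75-fold. The erythroid membrane gene Ermap fell 4.39-fold. The histone gene Hist1h2af was at 5.18, 3.14 and 5.23 RPKM in mixed wild type and at 0, 0.10 and 0 in cKO. The alpha globin gene Hba-a2 fell 4.37-fold, mt-Atp6 5.60-fold and Rpl35a 4.55-fold. These last 4 genes share sequence with other genes: 85.9%, 91.0%, 99.5% and 8.63% of their transcript's 31-base words occur in transcripts of other genes, and their values are uncertain.

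Of the 24 gene lists fixed in advance, 15 had members among the 190. All 4 measured surface ectoderm genes rose (median log2 fold change 2.12), and all 4 were called when adjusted over the list alone. All 4 were outside the inbred list and low in mixed wild type, where hardly any gene could be listed except by a rise, so their shared direction is not evidence about the list. The list did not stand apart from the other genes by camera (adjusted p = 0.168, and 0.353 with an estimated correlation). Camera compared a list only with the other genes of the 190, all listed as changed. Its results for this list and for the fibre list therefore say nothing about unlisted genes. Krt8 shared 32.3% of its 31-base words with other genes and Krt18 11.4%. Of the 4 measured fibre genes 3 fell and Lgsn rose, from 0.06 ± 0.02 to 3.63 ± 0.77 RPKM (SD, n = 3). All 4 were called adjusted over the list alone, with a median of -1.40, a mean of -0.48, pulled up by Lgsn, and camera adjusted p = 0.228 (0.353 with an estimated correlation). Signalling lists had 1 measured member each, and each rose and was called. With 1 gene there is nothing to adjust over, and each was listed for a difference between these same libraries. Dkk1, a secreted Wnt inhibitor, rose 12.1-fold, Cyr61, a matricellular gene of the TGF-beta list, 4.52-fold, the Notch list member Hes6 3.12-fold, and Dusp6, a feedback inhibitor of MAPK signalling, 3.06-fold. The integrin gene Itgb8 rose 3.38-fold and the immediate early list member Btg2 3.29-fold. Dkk1, Cyr61 and Itgb8 were outside the inbred list, where the listing largely fixes a rise. The shared direction of these single genes is therefore not evidence about their pathways. Under quantile normalization over the 190 genes Dsc2 (adjusted p = 0.0927), Cyr61 (0.627) and Itgb8 (0.402) were no longer called by limma.

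Markers of other cell types moved in both directions. Of 3 neuronal list genes Uchl1 rose while Elavl4, an RNA-binding protein gene, fell 6.01-fold and Stmn4, a stathmin gene, 8.65-fold. Both measured erythroid genes fell, Hba-a2 4.37-fold and Hba-x 4.10-fold. The endothelial receptor gene Tek rose 3.07-fold. Among loci that differ between laboratory strains, Pde6b rose and Fgfbp3 fell 2.16-fold. All of these were also called when adjusted over their own list alone, and Rpl19, the single measured ribosomal and housekeeping gene, was not. The crystallin list (Crygs, of 16 genes) and the muscle list (Tnnt1, of 21) also had a single measured member, which was called. All were listed for a difference between these libraries, so such calls were largely fixed beforehand. The 9 lists without a member among the 190 were lens epithelium, cell cycle, p53 targets, epithelial-mesenchymal transition, retina, pigment cells, macrophages, periocular mesenchyme and sex-linked genes. Of the 62 genes outside the inbred list 60 were higher in cKO, and Elavl4 and Arl5c were lower. The listing largely fixes this direction, since every one of the 190 genes had a mean of at least 2.14 RPKM in its higher group and the inbred list began at 2 RPKM.

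**Figure D2:**
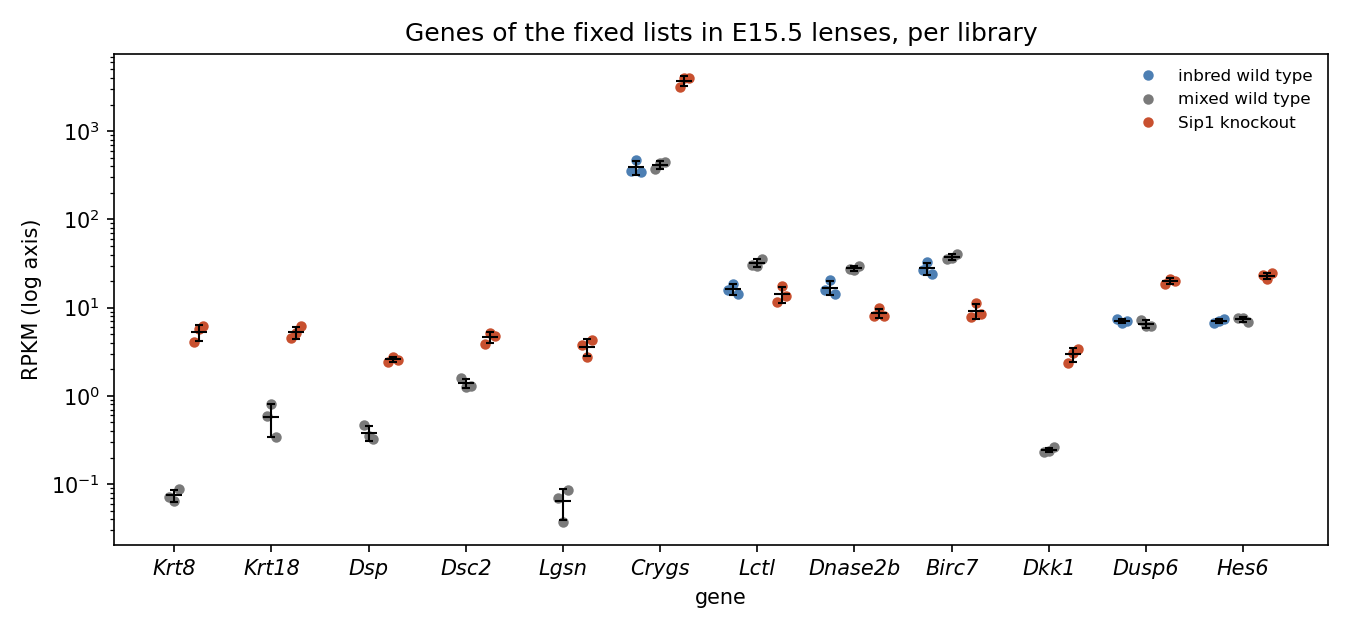
Expression of 12 genes of the fixed lists per library (points, RPKM on a log axis, genes on the horizontal axis) in inbred wild type (blue, where listed), mixed wild type (grey) and cKO (red), with mean and SD in black. The 3 cKO libraries lay above the 3 mixed wild type libraries for Krt8, Krt18, Dsp, Dsc2, Lgsn, Crygs, Dkk1, Dusp6 and Hes6, and below them for Lctl, Dnase2b and Birc7.

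The comparison of mixed with inbred wild type asked how far expression differs between wild types of different genetic background, which here also differ in depth, file type and floxed alleles. The fibre genes Lctl (1.96-fold), Dnase2b (1.66-fold) and Birc7 (1.34-fold) were higher in mixed wild type. Plxna1, a semaphorin receptor gene, was 1.82-fold lower and the vesicle traffic gene Rab6b 2.24-fold lower in mixed wild type. Crygs did not separate the wild types, at 416 ± 41.3 RPKM in mixed and 389 ± 70.9 RPKM in inbred wild type (SD, n = 3, limma adjusted p = 0.529).

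Limma called 63 of the 128 shared genes, with 39 higher and 24 lower in mixed wild type. At a minimum of 2-fold 3 remained, Ceacam10 and Gpx8 higher and Rab6b lower. In 73 genes, 57.0% of those tested, the 2 groups of libraries did not overlap. Chance gives 10% of unselected genes, and these were selected partly on the mixed wild type libraries. The balance of higher and lower calls depended on scaling: 28 higher and 29 lower under quantile normalization, 23 and 37 under median centring, and 71 and 9 with RPKM rescaled to the normalized values. That rescaling took the median normalized value per RPKM over the inbred list for inbred libraries. For mixed wild type it took the upper quartile over the 128 shared genes. A shift between the wild types may therefore be built into the balance of 71 and 9. The larger rises were Ceacam10 (log2 fold change 1.04, SE 0.14, limma adjusted p = 0.000449), Gpx8 (1.03), Ccdc23 (0.97), Lctl (0.95), the histone gene Hist1h2af (0.89), Tecrl (0.84), the mitochondrial gene Apoo (0.83) and Dpysl2 (0.76). Hist1h2af shares 85.9% and Apoo 46.8% of its 31-base words with other genes. The larger falls were Rab6b (-1.02), the spectrin gene Spna1 (-0.87), Plxna1 (-0.81), the sodium-calcium exchanger gene Slc8a1 (-0.67), Stac2 (-0.66), Fbxo10 (-0.65), Epn3 (-0.61) and Asap2 (-0.59).

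Of the list genes, Fgfbp3 was higher (log2 fold change 0.55) and Uchl1 1.22-fold lower in mixed wild type, and the called fibre genes Lctl, Dnase2b and Birc7 were the 3 of that list measured here. All 3 were called adjusted over the list alone. Hba-x (adjusted p = 0.071), Hba-a2 (0.104), Rpl19 (0.171), Stmn4 (0.470), Dusp6 (0.466), Hes6 (0.684), Btg2 (0.708) and Tek (0.982) were not called by limma. Several calls close to the threshold changed when a library was left out, with the direction of change kept. Slc8a1 was lost without mixed replicate 2 (adjusted p = 0.0625), inbred replicate 2 (0.0571) or inbred replicate 3 (0.112). Asap2 was lost without inbred replicate 2 (0.0606) or 3 (0.0954), and Birc7 without mixed replicate 3 (0.0517) or inbred replicate 3 (0.0598). Under quantile normalization Dnase2b (0.134), Birc7 (0.111), Slc8a1 (0.154) and Asap2 (0.145) were not called. Uchl1 was lost without mixed replicate 1 (0.076), mixed replicate 3 (0.149), inbred replicate 1 (0.0852) or inbred replicate 2 (0.0868). Hba-x was gained without mixed replicate 3 (0.0196) or inbred replicate 1 (0.045), Hba-a2 without mixed replicate 1 (0.0142) and Rpl19 without inbred replicate 1 (0.0445).

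The comparison of cKO with inbred wild type asked whether the knockout differences also hold against the other wild type. The largest rises among the 128 shared genes were Uchl1 (11.6-fold), Crygs (9.58-fold) and Myh7b (9.28-fold), followed by the glucagon gene Gcg (5.93-fold), Grtp1 (5.29-fold), Fam46b and Epn3 (both 5.22-fold) and the glutathione transferase gene Gsta4 (4.76-fold). Hes6 (3.23-fold), Btg2 (3.17-fold), Tek (3.06-fold) and Dusp6 (2.86-fold) were higher in cKO as well. Falls included the neuronal list gene Stmn4 (7.93-fold), Cend1 (5.78-fold), mt-Atp6 (5.30-fold), Actn2 (5.17-fold), Cnrip1 (4.88-fold) and Rbp3, which encodes a retinoid-binding protein (4.07-fold). Rcan2 (3.83-fold), Pgm5 (3.61-fold), Hba-a2 (3.60-fold), Birc7 (3.05-fold), Hba-x (2.83-fold), Dnase2b (1.95-fold) and Fgfbp3 (1.44-fold) were also lower.

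Limma called 120 of 128 genes here, 42 higher and 78 lower in cKO, and 76 of them changed by at least 2-fold. Not called were Lctl (log2 fold change -0.20, adjusted p = 0.202), Rpl19 (0.01, adjusted p = 0.892), Cbx6, Plxna1, Hnrnpa1, Tecrl, Ceacam10 and Gpx8. Lctl was called without cKO replicate 2 (adjusted p = 0.0231). All list genes measured here other than Lctl and Rpl19 were called when adjusted over their list alone. In 119 genes, 41 higher and 78 lower in cKO, the change against both wild types was called in the same direction. Both comparisons share the cKO libraries. Simulations of an unchanged cKO group gave at most 0 such genes, but did not repeat the selection of genes for a cKO difference, so they give no chance value for this list. Independent lists would share 14.1 higher and 51.2 lower genes, so part of the excess may come from the shared libraries.

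The differences of cKO and of inbred wild type from mixed wild type were then set side by side. All 63 genes called between the wild types were also called in cKO against mixed wild type. So were 127 of the 128 shared genes, which were listed for that difference, so the full overlap says nothing by itself. For 60 of them cKO and inbred wild type lay on the same side of mixed wild type, 21 above and 39 below (Fisher's exact test, two-sided p = 7.33e-14, which does not allow for the shared mixed wild type libraries or for genes that vary together). Over all 128 genes 86.7% lay on the same side, against a mean of 67% in the simulations of unchanged groups. The exceptions among the 63 were Adc, Gstp2 and the tubulin gene Tubb2b, below mixed wild type in cKO and above it in inbred wild type. Plxna1, Rab6b and Stac2 were among the genes above mixed wild type in both, and Lctl, Dnase2b and Birc7 among those below it. Across the 128 genes, which are not independent replicates, the correlation of the log2 differences from mixed wild type was 0.69. In 100 simulations of unchanged groups with shared wild type libraries it had a mean of 0.49 and a highest value of 0.69. The covariance was 0.51, against a simulated mean of 0.01. The simulations held neither a knockout effect nor the selection of genes. They therefore give no chance value for the correlation, the covariance or the share of genes on the same side. Independent lists would share 8.1 genes above and 25.6 below, and with 3 shared libraries part of the excess over these may come from sharing.

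**Figure D3:**
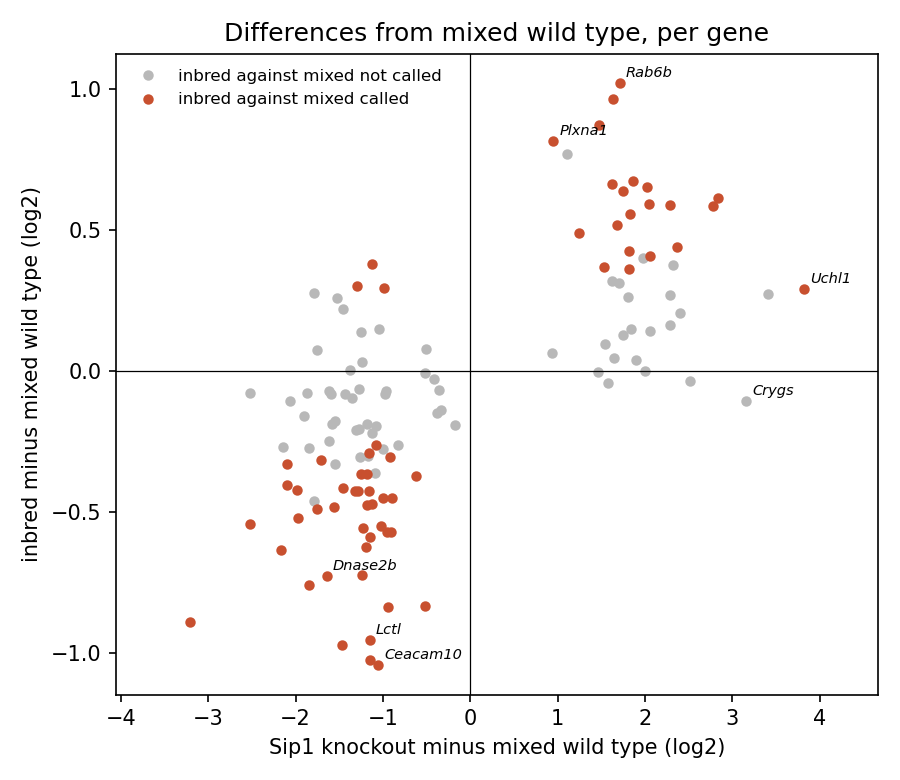
Log2 difference from mixed wild type in cKO (horizontal axis) and in inbred wild type (vertical axis) for the 128 genes listed in all libraries, on the log2(RPKM + 0.5) scale. Red points are the 63 genes called between the wild types, of which 60 lie at the upper right or lower left.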

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

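All tests in this part were chosen after the results were seen. The authors' normalized values, which the comparisons did not use, parted from RPKM by more than 1 on the log2 scale in 5 genes, after removal of the shift of -0.28 between cKO and mixed wild type libraries. The cKO over mixed wild type change was lower in the normalized values than in RPKM by -3.21 for Rpl34, -2.14 for Ndufb4, -1.71 for Rpl19 and -1.58 for Rpl39. It also differed by -1.70 for Lgsn, whose mean normalized value in mixed wild type was 3, close to the floor.

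Among genes with an exon length, a gap of at least 0.5 in the same direction was found in 15, among them Rpl11, Rpl37a, Rpl38, Hnrnpa1 and Apoo; Lgsn has such a gap too but no exon length and no shared words, so what follows leaves it out. Over 100 genes with few shared sequence words the 2.5th percentile of the gap was -0.087, against a median of -0.79 in the 15. The 15 were set aside beforehand, so this percentile could not reach a gap of 0.5 in that direction. Among the 100, Polr2b (0.78), Plxna1 (0.62) and Cbx6 (0.51) parted by more than 0.5 the other way. The authors' normalization therefore stays open as a part of the cause. All 15 share at least 10% of their 31-base words with other genes, against 12 of 112 others (Fisher's exact test, p = 1.49e-12). Normalized values that leave out reads shared between gene copies are thus a candidate for part of the gap. Sharing alone falls short: Rpl34, with the largest gap, shares 11.65% of its words. Gpx8 and Polr2b share 0%, yet were at 11.3% and 0.79% of the typical value in cKO. Leaving out shared reads alike in all groups would not by itself set cKO apart. Mixed wild type alone does not account for the gap: the normalized value per RPKM had a median log2 ratio of inbred over mixed wild type of -0.175, with Rpl19, Rpl37a and Rpl39 further apart, but was lower in cKO than in inbred wild type in 15 of 15 genes (median -0.79), with Rpl34 at 37.0% of the typical value in inbred, 33.8% in mixed wild type and 3.66% in cKO. The typical value was a median over the inbred list in inbred wild type and an upper quartile over the shared genes in the other groups. Small ratios of inbred wild type to the other groups are therefore uncertain. Read length, strain variants in these genes and a change in which copy is expressed stay open and untested, and the list itself was chosen on the normalized values.

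For 111 of 128 genes (86.7%, against a mean of 67% in simulations of unchanged groups) cKO and inbred wild type lay on the same side of mixed wild type. The shared mixed wild type libraries stay open as a part of the cause. The covariance was 0.51, against at most 0.0183 in the simulations, and the correlation was 0.69, which was also their highest. The simulations held no knockout effect and did not repeat the selection of the 190 genes, so they give no chance value for either. Library values did follow gene length within the wild type groups (rank correlation across genes -0.49 in inbred replicate 1, 0.45 in inbred replicate 3 and 0.56 in mixed replicate 1), but with a length trend removed the covariance was still 0.47, and 0.40 with the difference of inbred replicates 3 and 1 removed as well. Mixed wild type lenses further along in fibre maturation are a candidate explanation that these genes cannot decide. The 3 of 3 fibre genes measured in all groups (Birc7, Dnase2b and Lctl) were highest in mixed wild type. They are few and were listed as lower in cKO, and most of the 128 genes lay on the same side, so any such genes would tend to do this. Most of the 28 fibre genes in the inbred list were not among the 190. Lgsn, a fibre gene without an inbred value, and the crystallin gene Crygs were lower in mixed wild type than in cKO. Mixed wild type shared genetic background, floxed alleles and file type with cKO, so these alone would not place cKO with inbred wild type. Depth was highest in mixed wild type, and a library batch, which the labels do not give, was not tested. For the difference between the wild types alone, a library batch and genetic background cannot be told apart.

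Listed genes lay next to each other on chromosomes more often than in random draws. Among 7697 genes of both lists in genome order, 11 adjacent pairs belonged to the 190, against a mean of 4.66 in 10000 random draws (permutation test, p = 0.0076). The 62 listed genes outside the inbred list entered this order only by being listed. The draws therefore give no chance value for the 190. Pairs were also counted as independent, although Rpl19 paired with both Arl5c and Stac2. Krt8, Krt18, Tubb2a and Tubb2b share sequence with other genes, which the draws did not allow for. Dkk1 and Prkg1, Krt8 and Krt18, Tubb2a and Tubb2b, and Stmn4 and Dpysl2 were among the 8 pairs with the same sign, of which Arl5c and Rpl19 include a gene that was not called. DNA linked to the floxed Zeb2 locus is carried by both groups compared, so the design already removes that explanation, and 0 of 11 pairs lay within 25 listed genes of Zeb2. Single genes there were Gpd2, Dapl1 and Gcg, 3 against 1.23 by proportion in the same gene order, which has the same limit. Shared regulation of neighbours was not tested.

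The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes. It called 189 genes for cKO against mixed wild type, 63 for mixed against inbred wild type and 120 for cKO against inbred wild type, and the highest of the other splits called 0 in each. The genes were listed for a difference between cKO and mixed wild type, so that outcome was largely fixed beforehand for that comparison. The other comparisons used 128 of these genes, so none of the counts is independent support.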

How the results depend on the processing

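The normalized values, RPKM rescaled to them, the removal of genes of a low normalized value per RPKM (named in the tables as genes that share reads) and the restriction to genes in all 9 libraries were chosen after seeing the data. Of 110 values of the comparisons under alternatives 99 stayed within 1.5 times the reported count or on the same side of the threshold, and of 1909 values of named genes 1809 kept direction and call. Among the counts, cKO against mixed wild type moved from 189 to 100 genes without genes of a low normalized value per RPKM, which need not share reads. There 100 were tested, since the 62 genes outside the inbred list, which have no exon length, were dropped as well, and 127 of the 128 genes in all 9 libraries were called. The minimum folds of 2 and 2.5 left 3 and 0 genes for mixed against inbred wild type, 76 and 58 for cKO against inbred wild type, 75 and 55 changed the same way against both, and 3 and 0 on the same side of mixed wild type, by construction. The 0 arises at 2.5-fold with limma, where 75 of 128 genes have an unadjusted p under 0.05 with no minimum fold, and limma without trend called 60. By fry, which tests movement of a list's genes one way and not against other genes, the fibre list passed (adjusted p = 0.00252) and so did the ectoderm list (7.31e-05), which the selection of the 190 genes for a difference made likely beforehand.

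Leaving out each library in turn gave 185 to 190 genes for cKO against mixed wild type, 46 to 62 for mixed against inbred wild type, 118 to 121 for cKO against inbred wild type, 117 to 121 changed the same way, 43 to 60 on the same side and 5.56 to 6.14 RPKM for Zeb2. The replicate number does not pair the libraries: same-numbered libraries of cKO and mixed wild type correlated at -0.10, -0.11 and -0.15, those of the wild types at -0.52, -0.15 and -0.24, those of cKO and inbred wild type at -0.01, 0.24 and 0.20, and not every library correlated best with its own number. With the replicate block the counts were 189, 47 and 120.

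Reversed log2 fold changes, mostly of genes near 0, were as follows, and the cause was not tested. Under quantile normalization Rpl19 was 0.44 in cKO against mixed wild type, and Crygs -0.21 and Hes6 -0.068 between the wild types. Under median centring Crygs and Stmn4 were -0.04, Hes6 -0.10 and Tek -0.14 between the wild types, and Rpl19 -0.33 in cKO against inbred wild type. With rescaled RPKM, which took unlike reference values for the file types, Dusp6 was 0.18, Btg2 0.23 and Uchl1 0.005 between the wild types. With each library left out in turn Btg2 reached 0.032 without inbred replicate 3 and Tek ranged from -0.095 to 0.09 between the wild types (Tek -0.014 and -0.019 without mixed replicates 1 and 2), and Rpl19 from -0.046 to 0.112 in cKO against inbred wild type (-0.017 without cKO replicate 1, -0.021 without inbred replicate 2). The median log2 fold change of cKO over mixed wild type was 1.369 in the main fit. It was 0.191 under quantile normalization and 0.485 under median centring, since these assume an unchanged centre for genes that were chosen as changed. Depth was lowest in the inbred libraries, at 14.1 to 16.7 M reads, which limits the precision of low genes there most.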

Other observations

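Further genes among the 190 were picked after their values were seen, without a fixed list or a group test. Of genes for retinoic acid metabolism, 2 were higher in cKO than in mixed wild type: Aldh1a3, which makes retinoic acid, from 0.16 ± 0.04 to 6.38 ± 1.13 RPKM (SD, n = 3, limma adjusted p = 1.1e-09), and Cyp26a1, which breaks it down, from 1.70 ± 0.10 to 5.32 ± 0.36 RPKM (adjusted p = 7.9e-08). Both were outside the inbred list, where the listing largely fixes a rise, so their shared direction is not evidence about retinoic acid metabolism. Genes linked to axon guidance moved both ways. Dpysl2 fell 3.75-fold, while Plxna2 rose 26.7-fold, Plxna1 1.98-fold, the neogenin gene Neo1 2.99-fold and the gene of its ligand Rgmb 7.08-fold, and these 4 rises kept their direction under quantile normalization, median centring and in the normalized values. Plxna1 was no longer called under median centring, nor in cKO against inbred wild type. Plxna1 and Neo1 were also called lower in mixed than in inbred wild type. Plxna2 and Rgmb were outside the inbred list, where the listing largely fixes a rise.

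Of 12 ribosomal protein genes among the 190, 11 fell and Rpl19 was not called, with a median log2 fold change of -0.92, from -2.16 for Rpl35a to -0.18 for Rpl19. All 12 were lower in RPKM, under median centring and in the normalized values, and 10 of 12 under quantile normalization. Most fell by less than 2-fold. They were listed for a fall in the normalized values, part of which shared reads may explain (p = 1.49e-12 by Fisher's exact test for the genes with a gap), and the group says nothing about ribosomal genes outside the list. Their values are uncertain, since they share 8.63% (Rpl35a) to 79.9% (Rpl19) of their 31-base words with other genes. The 3 beta-tubulin genes Tubb2a, Tubb2b and Tubb4 fell by 1.25 to 1.38 on the log2 scale and were lower under each scaling. Tubb2a shares 56.4%, Tubb2b 45.9% and Tubb4 1.87% of its 31-base words with other genes, so the values of Tubb2a and Tubb2b are uncertain.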
